A study of Mus musculus with 3 samples.

How the data were processed

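Droplet single-cell RNA sequencing was run on CD45+ cells (leukocytes) from the lungs of wild-type mice, with the version 2 chemistry for 3' ends from 10x Genomics. Per the labels, mice were given PBS or 7.5 µg of Alt Ext on days 0, 3 and 6, and lungs were taken on day 7. Alt Ext is the name on the labels, which the study uses for an extract of the fungus Alternaria, a common airway allergen. Lungs were digested for 30 min at 37 °C with collagenase (2 mg/ml) and DNase (0.1%), and CD45+ cells were enriched on magnetic columns before sorting. 1 PBS library (PBS 1, female) and 2 Alt Ext libraries (Alt Ext 1, female, and Alt Ext 2, male) were used. How many mice stand behind each library is not given in the sources used here, so every p-value measures only the spread between these samples, which may be technical.

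The deposited matrices hold, for each cell barcode and gene, a count of unique molecular identifiers (UMIs, tags that mark single RNA molecules). The authors made these count matrices with Cell Ranger 3.0.2 per their processing notes, and the genome build is not given in the sources used here. No coordinates were therefore used, and a GENCODE mouse annotation served only to find genes that overlap a neighbour (27645 of 27998 gene identifiers were matched). The 3 libraries held 1614 barcodes: 609 in PBS 1, 439 in Alt Ext 1 and 566 in Alt Ext 2, with 2523152, 1852873 and 2147752 UMIs and medians of 3449, 3440 and 2880 UMIs per barcode. A gene with a UMI in 0 of 86 cells has an exact 95% bound of 4.20% for cells with a detected UMI. Cells that express it without a detected UMI are not bounded, so scarce genes were compared by summed counts.

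Barcodes with at least 200 genes and under 10% mitochondrial UMIs were kept, which left 570, 353 and 513 cells (1436 in all). In scanpy 1.11.5 under Python 3.11.15, counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1 with seed 0 gave 10 clusters. Metabolic, mitochondrial, ribosomal, sex-linked and dissociation-stress genes were kept out of the variable genes. A cluster was named where at least 3 of its 10 leading genes belong to a fixed marker list, and is otherwise called by number. No batch correction was used, and scrublet doublet calls (5, 14 and 11 cells) were kept. The pooled class of T-like cells planned for several comparisons did not pass its marker check, so it was replaced, after the data were seen, by the 6 clusters (0, 1, 2, 3, 6 and 9) in which over 50% of cells held a Cd3e UMI. These are called CD3-rich.

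UMI counts were summed per library over all cells, over the CD3-rich cells and over each cluster with at least 20 cells in every library (clusters 1, 2, 3, 6 and 7). Alt Ext was compared with PBS by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10) and Benjamini-Hochberg adjusted p under 0.05. With 1 PBS library, 1 residual degree of freedom comes from the Alt Ext pair, and the PBS library is assumed to vary like it. The fitted prior degrees of freedom were 13.1 over all cells. They were infinite in the CD3-rich cells, in every cluster and in the tests of a difference between cell sets, so there a gene that differs mainly between the Alt Ext libraries can still pass. Sex could not be fitted beside treatment. Levels are counts scaled to a common library size (CPM in edgeR), as the PBS value and the Alt Ext mean ± SD (n = 2). A gene with no PBS count is given as a lower bound against a floor of 3 counts per library, and a gene with 1 to 3 PBS counts as a ratio with its 95% counting interval. That interval takes UMIs as independent and leaves out the spread between cells, libraries and animals. Shares of cells carry exact binomial 95% intervals and no test, since a permutation of 3 libraries cannot pass 0.05.

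Fixed gene lists for metabolic pathways, lymphocyte and macrophage states, proliferation, stress and other cell types were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over 147 list and cell-set pairs. An estimated correlation and fry were run beside it. The estimated correlation rests on few residual degrees of freedom, 1 for Alt Ext against PBS. There its lowest adjusted p was 0.726 in every cell set, so that value decides neither for nor against a list. The test fry passed no list in any cell set, with lowest adjusted p from 0.183 to 0.547. The preset correlation takes the genes of a list as nearly independent. Genes that rise in the same few cells are not, so its p-values can overstate the evidence. For each list the genes past 0.05 are counted over all genes tested and adjusted over the list alone ("alone" after the first mention). Type 2 cells (any Il4, Il5 or Il13 UMI, or at least 2 UMIs over these with Il1rl1 and Gata3) and type 17 cells (any UMI of a fixed set of type 17 genes, Il17a, Il17f and Il23r among them) among the CD3-rich cells were compared within libraries with library as a block, without the gate genes. The same block served for CD3-rich cells against cluster 7, for cluster 3 against cluster 1, and for the difference of the Alt Ext effect between cell sets. The last pair of clusters and the use of cluster 7 in the difference test were chosen after seeing the data.

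Genes are named by a rule: among those past adjusted p 0.05 with the same sign in both Alt Ext libraries, the 10 largest rises and the 10 largest falls per cell set, without sex-linked and receptor variable genes, and a fixed set of targets such as Gata3, Il4, Ldha and Chil3. Where fewer pass, and in the counts by list, members of the fixed lists are named. Genes that define a cluster are not reported as results within it. The cell filter, tests, lists, targets and this rule were set before the data were examined.

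The test was checked on simulated data with 200 changed genes, drawn from genes with higher counts, and a coefficient of variation of 0.15. It recovered 66.7% (cluster 3) to 95.2% of genes changed by 2 on the log2 scale and 6.59% (cluster 3) to 44.2% of those changed by 1, with 3.76 to 8.57% of calls wrong and no call without a change. The simulation gave every gene and library the same spread and held no outlying single cells. The fitted coefficients ran from 0.110 in cluster 7 to 0.212 in cluster 6. The simulated error rates therefore do not carry over to the calls made here.

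Alternatives tried were size factors from DESeq2, library size alone, the Wald test of DESeq2 1.42.0, no count filter, at least 30 counts, mitochondrial and ribosomal genes left out, cells with 500 genes and under 5% mitochondrial UMIs, scrublet calls removed, Leiden resolutions 0.5 and 2, equal cell numbers, marker assignment per cell, at least 2 UMIs or thinning to 1000 UMIs for positive cells, no block, and each Alt Ext library left out. After seeing the data, barcodes shared between libraries left out, the bias-adjusted test of edgeR, cluster 3 left out, CD3-positive cells of cluster 7 left out, and clusters made without the 339 called genes were added. Left out were the 39, 86 and 53 barcodes of PBS 1, Alt Ext 1 and Alt Ext 2 with at least 10% mitochondrial UMIs. T cell receptor constant genes and most immunoglobulin constant genes were not used here.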

Results

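The study addresses which gene programmes, metabolic ones among them, T helper cells use in airway inflammation driven by Alt Ext. Mitochondrial UMIs made up at least 10% in 6.40% (95% interval 4.59 to 8.65) of PBS 1 barcodes, 19.6% (16.0 to 23.6) of Alt Ext 1 and 9.36% (7.09 to 12.1) of Alt Ext 2, and these barcodes were left out. Kept cells had medians of 3638.5, 4100 and 3136 UMIs. The X-linked gene Xist had 2230, 1831 and 13 UMIs in PBS 1, Alt Ext 1 and Alt Ext 2, and the Y-linked gene Eif2s3y 0, 0 and 171, as the labelled sexes require.

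Lung CD45+ cells formed 10 clusters, of which 6 held mostly cells with CD3 transcripts. Cluster 3, led by Tnfrsf4, Ctla4, Foxp3 and Ikzf2 (regulatory T-like, 204 cells), made up 5.09% (3.43 to 7.23) of PBS cells against 27.2% (22.6 to 32.2) in Alt Ext 1 and 15.4% (12.4 to 18.8) in Alt Ext 2. Foxp3, its lineage factor, had a UMI in 28.9% of these cells, Gata3 in 71.6% and Il4 in 20.6%, so the cluster holds more than regulatory T cells. Cluster 0, led by Cx3cr1, Zeb2, S1pr5 and Ccl5 (169 cells), went the other way: 22.1% (18.8 to 25.7) of PBS cells, 7.65% (5.10 to 10.9) of Alt Ext 1 and 3.12% (1.79 to 5.02) of Alt Ext 2. The proliferating cluster 9, led by Birc5, Ube2c and Top2a (65 cells), made up 2.63% (1.48 to 4.30), 5.95% (3.72 to 8.95) and 5.65% (3.82 to 8.02). Clusters made without the 339 genes called between Alt Ext and PBS placed 85.7% of cells alike. They gave 5.26%, 28.9% and 15.2% for cluster 3, 22.3%, 8.78% and 5.65% for cluster 0, and 3.51%, 7.08% and 5.85% for cluster 9. Marker scores per cell gave 23.9%, 12.2% and 14.2% for cells scored as CD8 T cells, the score set beside cluster 0. That is another set of cells, as Cd8a had a UMI in 34.9% of cluster 0 and Cd4 in 37.3%. Cells scored as regulatory T cells, set beside cluster 3, were 32 of 570, 60 of 353 and 62 of 513. The shares were not tested, and a permutation of 3 libraries cannot reach 0.05.

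Cluster 1 (Igfbp4, Dapl1, Ccr7 and Lef1, 336 cells) held 27.2% of PBS cells, 16.7% of Alt Ext 1 and 23.8% of Alt Ext 2, and 35.4%, 20.1% and 28.7% without the called genes. The NK-like cluster 7 (Klra8, Ncr1 and Klrb1c, 257 cells) held 15.1%, 14.4% and 23.4% (13.9%, 14.4% and 22.4% without them). The shares of cluster 2 (Xcl1, Cxcr3 and Cd160) and cluster 6 (Cd163l1, Blk and Tmem176a) depended on the method. Cluster 2 held 13.5%, 10.2% and 11.9%, and 6.67%, 6.80% and 8.19% without the called genes. Cluster 6 held 4.04%, 8.50% and 5.85%, and 2.81%, 4.82% and 2.73% without them. B-like cluster 4 (Cd79a, Ms4a1), ILC2-like cluster 5 (Il5, Arg1, Calca) and cluster 8 (Lyz2, Chil3) had 65, 43 and 40 cells. They fell short of 20 cells in at least 1 library, so Alt Ext was not tested within them, and clusters 4 and 8 entered only a test of the difference from CD3-rich cells.

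**Figure D1:**
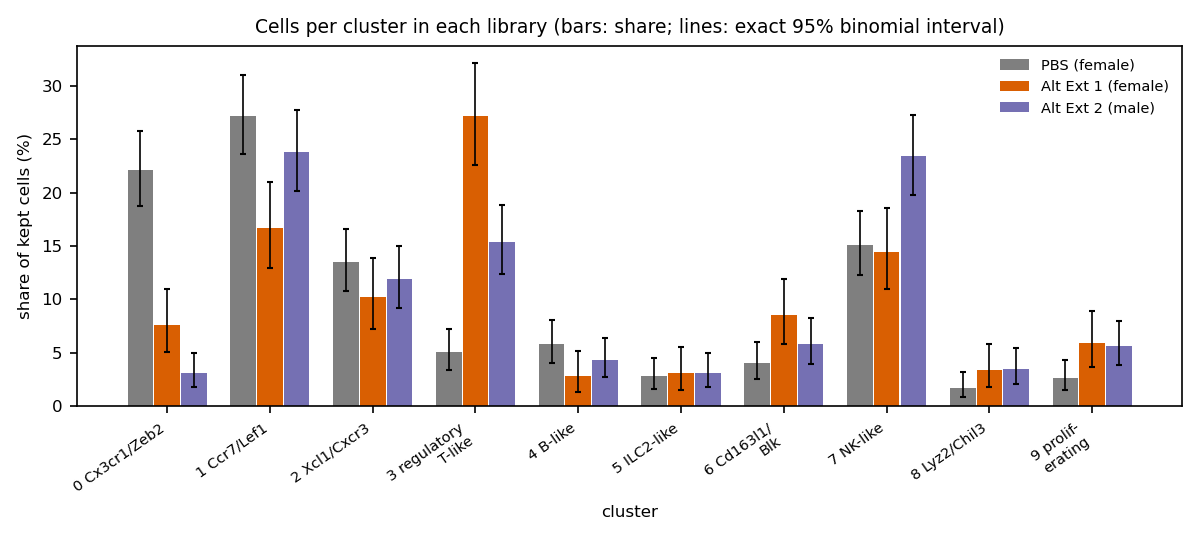
Share of kept cells in each cluster in PBS 1, Alt Ext 1 and Alt Ext 2, with exact 95% binomial intervals.

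Cells with type 2 cytokine transcripts were more frequent among the CD3-rich cells of both Alt Ext libraries. At least 1 UMI of Il4, Il5 or Il13 was found in 6 of 425 PBS cells (1.41%, 0.520 to 3.05), 40 of 269 Alt Ext 1 cells (14.9%, 10.8 to 19.7) and 23 of 337 Alt Ext 2 cells (6.82%, 4.38 to 10.1). Foxp3-positive cells made up 4.24% (2.53 to 6.61), 11.2% (7.65 to 15.5) and 8.90% (6.09 to 12.5), and Ifng-positive cells 19.5% (15.9 to 23.6), 10.0% (6.72 to 14.3) and 6.53% (4.14 to 9.72). Il17a or Il17f was found in 3, 9 and 1 cells (0.706%, 3.35% and 0.297%), with no direction shared by the Alt Ext libraries. Median depths of the CD3-rich cells were 3479, 4186 and 2991 UMIs. After thinning to 1000 UMIs per cell the shares were 0.493%, 6.32% and 3.08% for type 2, 0.985%, 5.14% and 4.31% for Foxp3, and 7.14%, 4.35% and 2.46% for Ifng. As background, the B-like cells (33, 10 and 22 cells, median 5933, 3315.5 and 2534 UMIs) held no type 2 or type 17 UMI (exact upper bounds of 10.6%, 30.8% and 15.4% for cells with a detected UMI). They held Foxp3 in 1 of 33 PBS cells and Ifng in 2 of 33. In the larger NK-like cluster 7, type 2 UMIs were in 0 of 86, 1 of 51 and 1 of 120 cells, and Ifng in 41.9%, 29.4% and 20.8%, or 9.41%, 18.0% and 12.8% after thinning.

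In the summed CD3-rich cells (425, 269 and 337), genes of type 2 helper cells rose with Alt Ext. Il4 (ENSMUSG00000000869), which encodes the cytokine that drives class switching to IgE, was 18.6-fold higher (log2 change 4.22, SE 0.42, adjusted p = 1.08e-20), at 4.74 CPM in PBS and 89.96 ± 63.9 CPM in Alt Ext. Il13 (ENSMUSG00000020383), a driver of mucus, had 3 UMIs in PBS, 147 in Alt Ext 1 and 51 in Alt Ext 2, a ratio of 39.7 (13.4 to 194). Il5, the growth factor of eosinophils, rose by 3.07 (SE 0.56, adjusted p = 7.49e-06). Gata3 (ENSMUSG00000015619), the transcription factor of the type 2 lineage, rose by 1.64 (SE 0.26, adjusted p = 8.36e-08), and Il1rl1, the receptor for the alarmin IL-33, by 2.68 (SE 0.39). Areg rose by 2.27 (SE 0.38), from 11.2 to 54.8 ± 20.1 CPM. Single cells weigh on the cytokines, which the counting interval does not take into account. Of the Il13 UMIs, 105 in Alt Ext 1 and 36 in Alt Ext 2 came from 1 cell each. The barcode of the former was also found in PBS 1, where it held 2 of the 3 Il13 UMIs. Without barcodes shared between libraries, the log2 change was 5.66 for Il13, 4.18 for Il4 and 2.98 for Il5, and Il5 no longer passed. Alt Ext 1 alone gave log2 changes of 4.81 for Il4, 5.85 for Il13 and 3.69 for Il5, and Alt Ext 2 alone 3.22, 4.27 and 1.98. Of the type 2 list 10 of 15 genes rose (12 adjusted over the list alone), with a median of 2.29 (camera adjusted p = 3.01e-37). With an estimated correlation, too short of degrees of freedom to decide, camera gave adjusted p = 0.726. By fry no list passed in these cells (lowest adjusted p = 0.271).

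Il10, an anti-inflammatory cytokine gene, and Lgals7 were among the other large rises in CD3-rich cells. Il10 had no UMI in PBS and 134 and 48 in Alt Ext, at least 36.9-fold higher (adjusted p = 8.61e-24). Lgals7 was 31.0-fold higher (log2 change 4.95, SE 0.43). Epas1 rose with a ratio of 44.6 (7.75 to 1783), the activation factor Irf4 with 35.5 (6.13 to 1427) and Igfbp7 with 24.1 (8.05 to 118). Kif15, Il1b and Klra8 also had no PBS UMI and were at least 5.97, 13.8 and 5.19-fold higher. However, 63 of 69 Il1b UMIs of Alt Ext 2 sat in 1 cell and Klra8 reversed to -0.54 at Leiden resolution 2. Of the regulatory T list 7 of 8 genes rose (7 adjusted over the list alone, median 1.75, camera adjusted p = 2.57e-31), among them Il2ra (2.00), Ctla4 (2.37) and Foxp3 (1.20, SE 0.34, adjusted p = 0.0172). Of the T cell activation list 7 of 12 rose (7 alone, median 0.85, adjusted p = 5.48e-12), such as Icos (0.97) and Pdcd1 (1.78). Proliferation genes rose in 8 of 19 (14 alone, median 0.74, adjusted p = 1.93e-13), with Birc5 at 1.53 and Mki67 at 1.05. With an estimated correlation, which passed no list in any cell set, these 3 lists had adjusted p = 0.726 each. With each cluster held at its PBS profile, cluster shares alone give 2.16 for Foxp3 (1.30 observed on that scale), 2.35 for Ctla4 (2.48) and 1.64 for Il2ra (2.10). They give 1.51 for Icos (1.07), 0.84 for Pdcd1 (1.89), 1.52 for Birc5 (1.64) and 1.64 for Mki67 (1.16). Without cluster 3, Il4 (3.21), Lgals7 (3.72) and Gata3 (0.99) still passed, while Il1rl1 (1.88), Foxp3 (0.94), Areg (0.42), Epas1 (4.34), Irf4 (6.52) and Chil3 (2.10) did not. Il13, Il5 and Il1b gave no value there.

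Leading genes of cluster 0, whose share was 22.1% in PBS 1 and 7.65% and 3.12% in Alt Ext, fell in the same CD3-rich cells. Zeb2, a transcription factor of terminal effector cells, fell by 2.33 (SE 0.24, adjusted p = 3.92e-19), from 225 to 44.8 ± 14.8 CPM, Cx3cr1 by 2.49 (SE 0.33, adjusted p = 1.41e-11) and S1pr5, which guides cells out of tissue, by 2.40 (SE 0.29). Ifng fell by 1.85 (SE 0.25, adjusted p = 1.78e-10), from 144 to 39.9 ± 24.8 CPM. Kcnj8 (-2.69), Tbkbp1 (-2.67), Apobec2 (-2.20), Hid1 (-2.16) and Borcs7 (-2.13) fell with them, as did Esm1 (-3.24), which overlaps Gzmk, and Ifitm1 (-2.75), with 44 of its 74 PBS UMIs in 1 cell. With each cluster held at its PBS profile, the change in cluster shares alone gives log2 changes of -1.90 for Zeb2 (-2.23 observed on that scale), -2.11 for S1pr5 (-2.31), -1.90 for Ifng (-1.76) and -1.54 for Cx3cr1 (-2.40). For Borcs7 it gives -0.32 (-2.03). Alt Ext 1 alone gave -2.02 for Zeb2, -1.83 for Cx3cr1, -1.94 for S1pr5 and -1.32 for Ifng, and Alt Ext 2 alone -2.71, -3.66, -3.06 and -2.67. Of the type 1 list 4 of 8 genes fell (5 adjusted over the list alone), Tbx21, Ifng, Ccl5 (-2.01, SE 0.12) and Nkg7, and Gzmb rose (1.45), with a median of -1.19 (camera adjusted p = 4.15e-06). Of the naive T list 4 of 8 fell, Ccr7 (-0.85), Lef1 (-0.78), Klf2 (-0.96) and Igfbp4 (-0.90), with a median of -0.60 (adjusted p = 1.6e-05). Alt Ext 2 alone gave -0.40 for the naive list. With an estimated correlation both lists had an adjusted p = 0.726. In all, 177 genes rose and 104 fell of 8465 tested by edgeR, against 34 by DESeq2. Among the edgeR calls 3 were sex-linked genes, which follow sex.

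**Figure D2:**
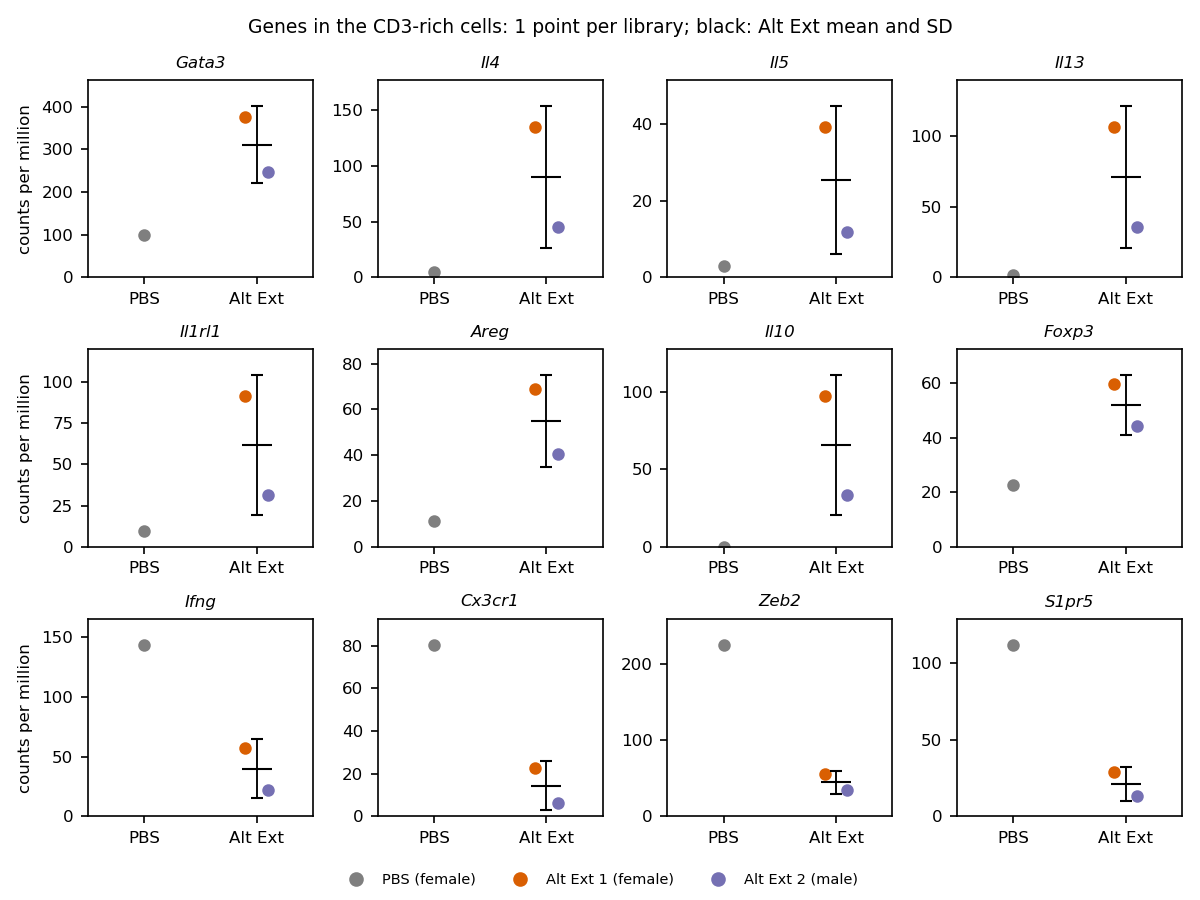
CPM of 12 genes in the summed CD3-rich cells, 1 point per library, with the Alt Ext mean and SD (n = 2) in black.

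A few metabolic genes rose as well. Tpi1 rose by 0.98 (SE 0.26, adjusted p = 0.009) and Gapdh by 0.66 (SE 0.20, adjusted p = 0.034) in the CD3-rich cells. The change in cluster shares alone gives 0.56 of 1.09 for Tpi1, 0.67 of 0.76 for Gapdh and 1.24 of 1.43 for the one-carbon gene Tyms. Of the glycolysis list these 2 of 18 genes rose (3 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.0184). The lipid genes Pparg (3.58, SE 0.57) and Fabp5 (1.91, SE 0.34) were the 2 of 15 fatty acid oxidation genes that rose (3 alone, median 0.21, adjusted p = 0.00354). Tyms (1.32) was the 1 of 9 one-carbon genes that rose (1 alone, median 0.54, adjusted p = 0.00149). Srebf2 (1.08) was the 1 of 13 genes of fatty acid and sterol synthesis (1 alone, median 0.48, adjusted p = 0.0293) and Cycs (0.78) the 1 of 42 nuclear genes of oxidative phosphorylation (0 alone, median 0.22, adjusted p = 0.0091). Alt Ext 2 alone gave medians of 0.15 for sterol synthesis, 0.10 for nuclear oxidative phosphorylation and 0.34 for fatty acid oxidation, and Alt Ext 1 alone 0.93, 0.31 and 0.23. Pparg also belongs to the type 2 list and Tyms to the proliferation list. With an estimated correlation these lists had adjusted p = 0.726, or 0.873 for oxidative phosphorylation. Among the targets Ldha (0.63, SE 0.21, adjusted p = 0.0851) and Slc2a1 (1.13, SE 0.50, adjusted p = 0.298) did not pass. Hk2 (0.33, adjusted p = 0.961) and Cpt1a (0.21, adjusted p = 0.947) did not either. The lists for the TCA cycle (20 genes, median 0.23, adjusted p = 0.302), mitochondrially encoded oxidative phosphorylation (13 genes, adjusted p = 0.876) and glutaminolysis (10 genes, median 0.38, adjusted p = 0.19) did not pass. Amino acid transport (5 genes, median -0.55, adjusted p = 0.0646), the pentose phosphate pathway (7 genes, median 0.29, adjusted p = 0.221) and mTORC1 and MYC targets (13 genes, median 0.01, adjusted p = 0.761) also missed the threshold. On simulated data of this size 39.3% of genes changed by 1 on the log2 scale were recovered, but those genes had higher counts and a uniform spread. The rate does not carry over to scarce metabolic genes such as Slc2a1, so shifts of that size can have been missed.

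Smaller lists in the CD3-rich cells rested on few genes. Of alternative macrophage genes 4 of 5 rose (5 adjusted over the list alone, median 2.15, or 1.78 with genes absent from PBS at their bound, camera adjusted p = 2.68e-08): Chil3 (2.52, SE 0.66, adjusted p = 0.00775, 5, 18 and 31 UMIs), Pdcd1lg2 (2.15), Cish (1.55) and Socs2 (1.25). Chil3 also leads the Lyz2 cluster 8, and whether CD3-rich cells made its few UMIs here was not tested. Hif1a (1.39, SE 0.28) was the 1 of 6 hypoxia genes that rose (2 alone, median 0.85, adjusted p = 0.00405). Cish and H2-Aa (1.29) rose in the list of IL-4 targets of B cells (2 of 3, 2 alone, median 1.29, adjusted p = 0.00354), and H2-Aa in that of MHC class II (1 of 5, 3 alone, median 0.76, adjusted p = 0.0156), but Alt Ext 1 alone gave a median of 0.08 for each. In the difference test below, H2-Aa had 13.5 CPM in PBS, 14.3 in Alt Ext 1 and 52.1 in Alt Ext 2. Most of its Alt Ext 2 UMIs came from 1 cell of cluster 6. Interferon genes had a median of -0.51 (1 of 13, Ifi204, rose; adjusted over the list alone 1 rose and 4 fell; adjusted p = 0.00202), and Alt Ext 1 alone gave -0.04. Alt Ext 2 alone gave -1.18 for interferon, 1.35 for MHC class II and 0.48 for hypoxia. Each of these lists had an adjusted p = 0.726 with an estimated correlation. The type 17 list (7 genes, median 0.31, adjusted p = 0.309) did not pass, nor did Il17a (1.34, adjusted p = 0.438). Inflammatory macrophage genes (5, with Il1b alone rising, adjusted p = 0.283), the sex-linked genes (6, of which 3 were called, adjusted p = 0.278) and dissociation stress (15 genes, adjusted p = 0.113) did not pass as lists. In the last, 5 genes fell, among them Fos (-0.74) and Jun (-1.11), and 2 rose, Ier3 (3.53) and Nr4a1 (0.97). Cd74 (0.38, adjusted p = 0.647) was not called.

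**Figure D3:**
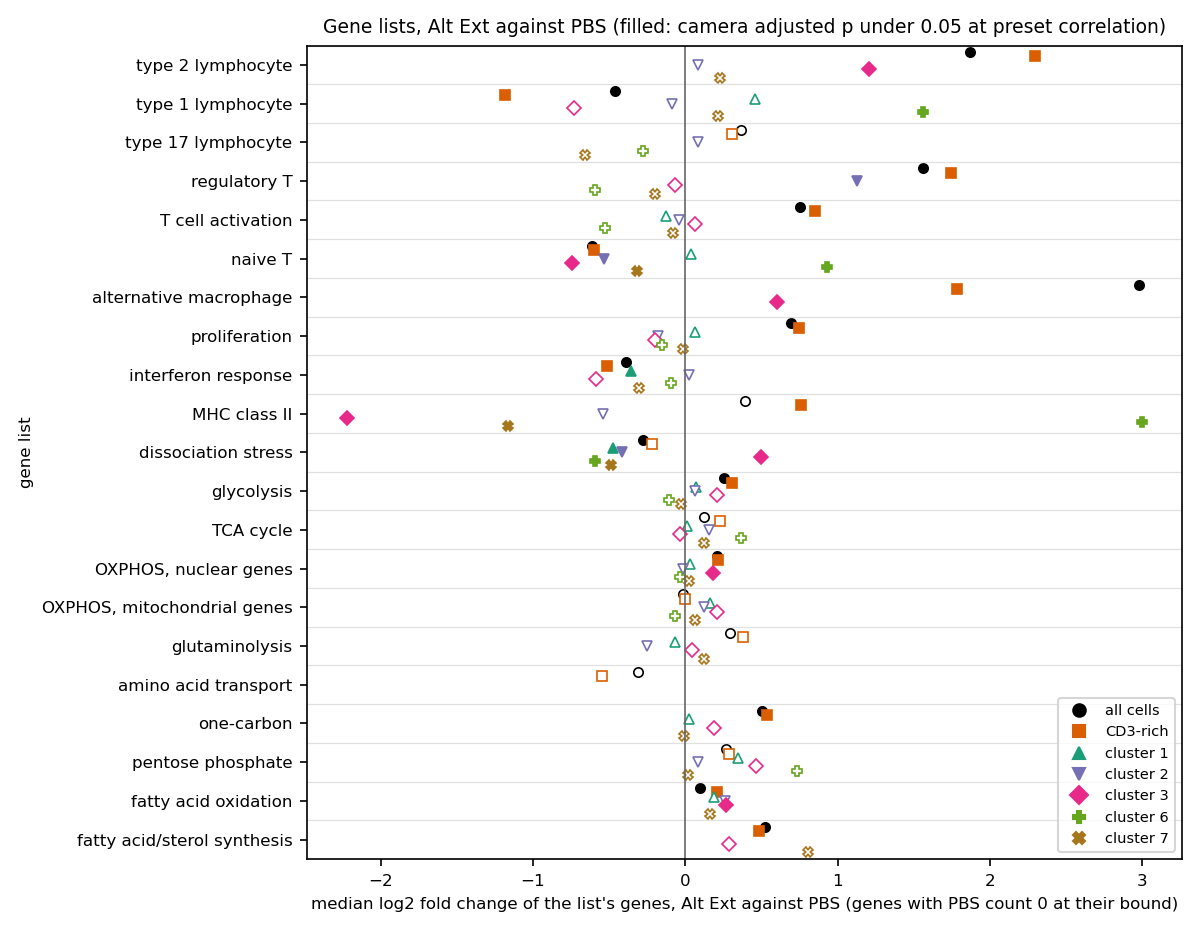
Median log2 change, Alt Ext against PBS, of the genes of each fixed list in each cell set, with genes absent from PBS at their bound; filled points passed camera at adjusted p 0.05 with the preset correlation.

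Within the regulatory T-like cluster 3 (29, 96 and 79 cells), Lgals7, Il4 and Il13 rose as well. At Leiden resolution 2, 3 clusters overlap it most, among them a Foxp3 group (16, 40 and 37 cells) and an Il4 and Lgals7 group (3, 47 and 23 cells), so the libraries bring different mixtures. Lgals7 had no UMI in PBS and 157 and 76 in Alt Ext, at least 8.45-fold higher (adjusted p = 5.31e-09). Il4 rose with a ratio of 10.6 (2.88 to 87.8; adjusted p = 0.000287) on 2, 165 and 23 UMIs, and Il13 with 7.03 (2.37 to 34.4; adjusted p = 0.00119). For Il4, Alt Ext 2 alone gave a log2 change of 1.65 and Alt Ext 1 alone 3.93. Il10 (at least 4.83-fold), the thrombin receptor F2r (at least 4.36-fold), Pdlim4 (at least 2.28-fold), Stoml2 (at least 2.22-fold) and Asb2 (at least 2.14-fold) were absent from PBS. So was Il1b (at least 3.04-fold), whose 65 UMIs in Alt Ext 2 include 63 of 1 cell. Ifitm3, Myo6 and Timp2 rose with ratios of 16.9 (3.00 to 674), 12.8 (2.25 to 510) and 12.2 (2.15 to 488); Alt Ext 2 alone gave 1.11 for Ifitm3 on the log2 scale. Gzmb (1.95, SE 0.33), Plac8 (2.51) and the nuclear oxidative phosphorylation gene Atp5g1 (1.43) rose too. Ccl5 (-1.82, SE 0.26, adjusted p = 8.25e-09), Klrg1 (-1.83, SE 0.31, adjusted p = 4.48e-06), Il18r1 (-2.26), Cry1 (-2.47), Nrf1 (-2.45), Eif2ak1 (-2.20), Ttc39c (-2.09), Polr2a (-1.90) and Nucks1 (-1.46) fell. So did Cd74 (-2.34, SE 0.33), with 23 of its 45 PBS UMIs in 1 cell. Gata3 (0.70, adjusted p = 0.323), Il1rl1 (0.77, adjusted p = 0.601), Areg (0.50, adjusted p = 0.791), Il5 (ratio 2.66, adjusted p = 0.489) and Ldha (0.54, adjusted p = 0.341) did not pass.

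By edgeR 36 genes rose and 26 fell of 5562 tested in cluster 3, against 0 by DESeq2. The type 2 list (4 of 14 rose; 7 adjusted over the list alone) had a median of 1.35, or 1.21 at the bounds (camera adjusted p = 1.77e-08), and Alt Ext 2 alone gave 0.60. The naive T list (1 of 7 fell, Klf2 at -0.82; adjusted over the list alone 1 rose and 3 fell; median -0.74, adjusted p = 0.00177) and MHC class II (1 of 5 fell, Cd74, 3 alone, median -2.22, adjusted p = 1.75e-06) were lower. Nuclear oxidative phosphorylation (1 of 42, median 0.18, adjusted p = 0.0354), fatty acid oxidation (0 of 15, 1 alone, median 0.61, or 0.27 at the bounds, adjusted p = 0.04) and mTORC1 and MYC targets (0 of 13, 2 alone, median 0.46, 13 above 0, adjusted p = 0.00244) were higher. Dissociation stress (0 of 14, 6 alone, median 0.50, adjusted p = 0.0107) and alternative macrophage genes (0 of 4, 1 alone, median 4.16, or 0.60 at the bounds, adjusted p = 0.00354) were higher as well. With an estimated correlation all had adjusted p = 0.726, or 0.873 for oxidative phosphorylation. Alt Ext 2 alone gave medians of -0.37 for naive T, 0.027 for nuclear oxidative phosphorylation and 0.39 for fatty acid oxidation, and Alt Ext 1 alone 0.76 for mTORC1 and MYC targets. Glycolysis (13 genes, median 0.21, adjusted p = 0.238) did not pass.

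Few genes changed in the clusters of Ccr7 and of Xcl1 cells. In cluster 1, Fos, an immediate early transcription factor, fell by 1.62 (SE 0.29, adjusted p = 9.23e-05), from 465 to 154 ± 27.7 CPM. Xist, which follows sex, was the other of 2 calls among 3867 genes. Jun (-1.15, adjusted p = 0.0658), Gata3 (0.24) and Ldha (0.07) did not pass. The dissociation stress list fell there (1 of 12, 5 adjusted over the list alone, median -0.48, camera adjusted p = 4.97e-10; adjusted p = 0.726 with an estimated correlation), while the interferon list had adjusted p = 0.0495 (0.732 with an estimated correlation) with a median of -0.36, or 0.019 with Alt Ext 1 alone. In cluster 2, the signalling regulator Rgs1 (1.67, SE 0.36) and the Fc receptor chain Fcer1g (1.66, SE 0.36; 182 to 575 ± 16.2 CPM) rose, each with adjusted p = 0.00451 (Rgs1 by 0.86 with Alt Ext 2 alone and 2.26 with Alt Ext 1 alone), and Ppp1r15a fell by 1.66 (SE 0.39, adjusted p = 0.0205). Myo6 (3.06; 4, 27 and 3 UMIs) and Hist1h2ap (1.97) rose and Ifitm1 fell on the UMIs of few cells, 28 of 41 for Hist1h2ap and 44 of 56 for Ifitm1 in 1 cell. The lists gave regulatory T higher (0 of 5, 1 alone, median 1.13, adjusted p = 0.0053), naive T lower (0 of 8, 4 alone, median -0.53, adjusted p = 3.8e-06) and dissociation stress lower (0 of 13, 3 alone, median -0.42, adjusted p = 0.000212), each at adjusted p = 0.726 with an estimated correlation. Alt Ext 1 and Alt Ext 2 alone gave medians of 0.45 and 0.68 for regulatory T and -0.94 and -0.33 for naive T. Of 3355 genes 5 rose and 2 fell. DESeq2 called 0 in both clusters, where 122 and 105 genes had an unadjusted p under 0.05 by edgeR.

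In cluster 6 (Cd163l1, Blk, Tmem176a; 23, 30 and 30 cells), Rgs1 rose by 2.49 (SE 0.49, adjusted p = 0.000234), the chemokine gene Ccl5 by 1.97 (SE 0.46, adjusted p = 0.00313) and Actb by 0.97 (SE 0.19). Ms4a6b (ratio 8.63, 2.82 to 43.0), Ly6a (2.29), Gimap4 (1.90), AW112010 (1.59) and Ifi27l2a (1.55, but 0.23 with Alt Ext 2 alone) rose and Fosb fell by 2.87 (SE 0.67, adjusted p = 0.00313). H2-Eb1, Cd74, H2-Aa and H2-Ab1 also passed, on 1 cell of Alt Ext 2 with 39, 176, 58 and 46 UMIs, and the MHC class II list (4 of 4, median 3.50, or 3.00 at the bound, camera adjusted p = 9.58e-08) had a median of -1.82 with Alt Ext 1 alone. Il17a (0.85) did not pass, nor did the type 17 list (8 genes, median -0.28, adjusted p = 0.157). Type 1 genes (1 of 3, 2 adjusted over the list alone, median 1.56, adjusted p = 0.000299, 0.72 with Alt Ext 1 alone) and naive T genes (4 genes, median 0.93, adjusted p = 0.0144) were higher and dissociation stress (1 of 11, median -0.59, adjusted p = 0.00976, -0.31 with Alt Ext 1 alone) lower. With an estimated correlation all 4 lists had an adjusted p = 0.726. In all 12 genes rose and 2 fell of 1492, with 1 sex-linked gene among them, against 0 by DESeq2 (70 at an unadjusted p under 0.05 by edgeR).

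NK-like cells (cluster 7; 86, 51 and 120 cells) carried more transcripts of granzymes. Gzmb rose by 1.12 (SE 0.19, adjusted p = 8.11e-06) and Gzma by 0.44 (SE 0.07, adjusted p = 8.96e-08), with Plac8 (2.25, SE 0.42), Hmgn2 (1.23), Sh2d2a (1.06), AW112010 (0.46), AY036118 (1.44), which overlaps Gm42418, and Tsc22d1 (ratio 10.1, 2.57 to 86.9). Fos fell by 1.25 (SE 0.23, adjusted p = 3.09e-05) and Jun by 1.17 (SE 0.22, adjusted p = 3.98e-05), with Klf6 (-0.89) and Pop5 (-1.43). Alt Ext 2 alone gave 0.66 for Gzmb, 0.23 for Gzma and 0.59 for Plac8, and Alt Ext 1 alone 1.51, 0.62 and 3.37. Ifi27l2a (-2.67), Cd74 (-2.46, with 61 of its 73 PBS UMIs in 1 cell), Cd8b1 (-1.49) and Lat (-1.16) fell as well. Part of these changes went with T cell transcripts: 28 of 86 PBS cells, 10 of 51 and 38 of 120 held a UMI of Cd3e, Cd3d or Cd3g. Without these cells Fos (-1.10, adjusted p = 0.0125), Jun (-1.29, adjusted p = 0.000646) and AY036118 (1.77) still passed. Gzma (0.33, SE 0.19, adjusted p = 0.989), Gzmb (0.80, SE 0.24, adjusted p = 0.135) and Plac8 (1.64, SE 0.85, adjusted p = 0.989) did not. Their changes kept direction, with larger SE than before. Log2 ratios of summed UMIs were then 0.25 (-1.59 to 2.40) for Ifi27l2a, -0.18 (-1.47 to 1.19) for Cd74 and -0.18 for Lat. They were 0.29 (0.21 to 0.36) for Gzma, 0.68 (0.39 to 0.97) for Gzmb and 1.61 (0.056 to 3.597) for Plac8. With all cells of the cluster these were 0.37, 0.99 and 2.12. The counting intervals leave out the spread between cells and libraries. Ifng (0.14, adjusted p = 0.983) and Ldha (-0.04) did not pass. Dissociation stress (2 of 13 fell, 7 adjusted over the list alone, median -0.49, -0.95 with Alt Ext 1 alone, camera adjusted p = 2.67e-11), MHC class II (1 of 4 fell, 2 alone, median -1.17, adjusted p = 0.000631) and naive T (0 of 8, 1 alone, median -0.32, adjusted p = 0.00814) were lower, with adjusted p = 0.726 each under an estimated correlation. In all 9 genes rose and 10 fell of 5379, with 2 sex-linked genes among them, against 0 by DESeq2 (285 at an unadjusted p under 0.05 by edgeR).

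Summed over all cells, which adds the NK-like, B-like, ILC2-like and Lyz2 cells, Il4, Il5, Il13, Areg and Gata3 rose, with several chemokine genes. Il13 had a ratio of 61.4 (20.8 to 300) and Il4 rose by 4.32 (SE 0.75, adjusted p = 0.0123), with 5.0002 for Alt Ext 1 alone and 3.15 for Alt Ext 2 alone. Il5 rose by 3.54 (SE 0.44, adjusted p = 0.0013), Areg by 1.86 (SE 0.28, adjusted p = 0.0048) and Gata3 by 1.36 (SE 0.26, adjusted p = 0.0251; 109 to 279 ± 81.2 CPM). Single cells held 105 of 152 Il13 UMIs in Alt Ext 1 and 92 of 150 in Alt Ext 2, 44 of 83 and 110 of 193 for Il5, and 40 of 189 and 32 of 66 for Il4. Chil3, a chitinase-like protein of macrophages, rose by 2.98 (SE 0.26, adjusted p = 6.43e-05), from 17.2 to 136 ± 6.28 CPM, with 169 of 227 and 221 of 305 UMIs in 1 cell each. Il10 (at least 40.1-fold) and the neutrophil attractant Cxcl3 (at least 17.4-fold) had no PBS UMI. Ccl24 (ratio 41.5, 7.20 to 1663), Ccl17 (22.0, 5.87 to 185), Ccl1 (34.2, 11.5 to 167; 112 of 150 UMIs of Alt Ext 2 in 1 cell), Il1r2 (36.0, 6.22 to 1446) and Igfbp7 (25.6, 8.57 to 126) rose. So did Il4i1 (26.9, 7.22 to 225), which overlaps Nup62, and Lgals7 (34.3-fold, log2 change 5.10, SE 0.77, adjusted p = 0.00451). Cx3cr1 (-1.90, SE 0.28), S1pr5 (-1.57, SE 0.21) and Zeb2 (-1.49, SE 0.19) fell, with Ifitm1 (-2.45), Apobec2 (-2.42), Tbkbp1 (-2.35), Kcnj8 (-2.10), Lamb3 (-1.36), Dtx1 (-1.35) and A430078G23Rik (-1.32). Il1rl1 (2.14, adjusted p = 0.0506), Arg1 (1.97, adjusted p = 0.0505) and Ifng (-1.13, adjusted p = 0.0549) missed the threshold. Foxp3 (1.21, adjusted p = 0.164), Il17a (1.37, adjusted p = 0.559) and Ldha (0.58, adjusted p = 0.379) did not pass. Nor did Slc2a1 (0.89), Hk2 (0.79), Cpt1a (0.17), Retnla (at least 3.44-fold, adjusted p = 0.486), Ear2 (ratio 11.3, 2.91 to 96.7, adjusted p = 0.155) or Cd74 (-0.02).

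Over all cells 63 genes rose and 23 fell of 9413, against 27 called by DESeq2 and 2 by edgeR with scrublet doublet calls removed. Type 2 genes (7 of 18 rose, 12 adjusted over the list alone, median 1.87, camera adjusted p = 2.82e-36), alternative macrophage genes (4 of 11, 10 alone, median 3.44, or 2.98 at the bounds, adjusted p = 5.07e-25) and regulatory T (5 of 8, 7 alone, median 1.56, adjusted p = 4.13e-25) were higher, as were T cell activation (4 of 12, 7 alone, median 0.75, adjusted p = 1.59e-09) and proliferation (2 of 19, 13 alone, median 0.69, adjusted p = 5.12e-14). One-carbon genes (1 of 10, median 0.50, adjusted p = 0.0008), fatty acid oxidation (2 of 17, median 0.10, adjusted p = 0.00378) and fatty acid and sterol synthesis (0 of 16, 1 alone, median 0.52, adjusted p = 0.00997) were higher by less. So were glycolysis (0 of 18, median 0.25, adjusted p = 0.0421), nuclear oxidative phosphorylation (0 of 42, median 0.21, adjusted p = 0.00976), hypoxia (8 genes, median 0.59, adjusted p = 0.0335) and IL-4 targets of B cells (1 of 5, 2 alone, median 0.38, adjusted p = 0.000299). Naive T (1 of 8 fell, 4 alone, median -0.61, adjusted p = 9e-07), type 1 (1 of 8 fell, median -0.46, adjusted p = 0.00877), interferon (0 of 14, median -0.39, adjusted p = 0.021; -0.04 with Alt Ext 1 alone) and dissociation stress (2 of 16 fell, median -0.28, mean 0.10, adjusted p = 0.0354) were lower. Alt Ext 1 and Alt Ext 2 alone gave medians of -0.43 and -0.16 for dissociation stress, 0.16 and 0.21 for fatty acid oxidation, 0.71 and 0.19 for sterol synthesis, and 0.29 and 0.092 for oxidative phosphorylation. For interferon, Alt Ext 2 alone gave -0.74. With an estimated correlation these had adjusted p = 0.726, except 0.873 for oxidative phosphorylation and 0.783 for interferon. Not past the threshold were the TCA cycle (adjusted p = 0.192), mitochondrially encoded oxidative phosphorylation (0.937), glutaminolysis (0.262), amino acid transport (0.179), the pentose phosphate pathway (0.134), type 17 (0.157), inflammatory macrophage (0.19), MHC class II (0.0623), mTORC1 and MYC targets (0.995) and sex-linked genes (0.232). Lists of eosinophil, neutrophil, mast cell, epithelial, endothelial, erythroid and platelet genes had 1 or 2 tested genes each, of which the neutrophil gene Il1r2 was called, and no fibroblast gene was tested.

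Cells gated as type 2 and type 17, compared within each library, differed in 31 genes, and no metabolic list passed. Fine clusters (Leiden resolution 2) picked by Il13 or a type 17 marker gave 173 genes and 3 metabolic lists within the Alt Ext libraries. None of the 3 passed with an estimated correlation. Most gated type 2 cells held no Il4, Il5 or Il13 UMI and entered on Gata3 and Il1rl1 UMIs. The fine Foxp3 group carried these too (Gata3 in 63.4% and Il1rl1 in 31.2% of cells). The gate can therefore include regulatory T cells. The 11, 12 and 10 type 17 cells carried more Cd163l1 (log2 change, type 2 over type 17, -6.12), Blk (-5.80), Tmem176b (-4.53), Serpinb1a (-4.35), the cytokine receptor Il7r (-1.83), Cxcr6 (-1.67) and S100a4 (-1.24) than the 37, 97 and 72 type 2 cells. The latter carried more Gzmb (3.19, SE 0.64), Cd28 (2.27, SE 0.48), Cd2 (1.46), Ms4a4b (1.73) and Ube2c (3.29). These genes were picked from the 8 higher and 23 lower of 1883 tested after their values were seen, and most type 17 cells lay in cluster 6, whose leading genes Cd163l1, Blk and Tmem176b are. Ldha (0.84, adjusted p = 0.171), Gapdh (0.56, adjusted p = 0.419) and Pkm (0.01, adjusted p = 0.989) did not pass, and Slc2a1, Hk2 and Cpt1a were too scarce to test. Of 7 metabolic lists 0 passed camera (lowest adjusted p = 0.637), with medians of 0.20 for glycolysis (10 genes), 0.40 for the TCA cycle (9 genes) and -0.12 for mitochondrially encoded oxidative phosphorylation (10 genes). Leaving out 1 library changed the number of called genes from 31 to between 3 and 48.

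Metabolic lists were also compared between cell sets, where 2 of 8 passed for cluster 3 against cluster 1 and 1 of 10 for CD3-rich cells against cluster 7. Against cluster 1, the cells of cluster 3 had more Gapdh (1.35, SE 0.12), Tpi1 (1.33), Ldha (1.16, SE 0.14) and Pgam1 (1.02), and 7 of 11 glycolysis genes were higher (7 adjusted over the list alone, median 0.56, camera adjusted p = 0.00541). All 12 tested mitochondrially encoded genes were lower in cluster 3, such as mt-Cytb (-0.75) and mt-Co1 (-0.64), with a median of -0.90 (adjusted p = 2.32e-10). Library size scaling raised the median of all genes by 0.51, and the list medians became 1.07 and -0.39. In the CD3-rich cells against NK-like cluster 7, 11 of 12 mitochondrially encoded genes were higher (12 adjusted over the list alone, median 0.56, adjusted p = 3.14e-05), such as mt-Cytb (0.66), while glycolysis genes went both ways, with Gapdh (0.87) and Ldha (0.74) higher and Tpi1 (-0.68) and Pfkp (-0.69) lower. With an estimated correlation the adjusted p was 0.531 for both lists of the first pair and 0.791 in the second. In all 527 genes were higher and 520 lower of 3925 in cluster 3 against cluster 1, and 544 and 505 of 6944 in CD3-rich cells against cluster 7.

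The change between PBS and Alt Ext differed between the pooled CD3-rich cells and NK-like cluster 7 for 68 of 6944 genes in a test of the difference. Zeb2 changed by -2.31 in CD3-rich cells and 0.03 in cluster 7, Ccl5 by -2.01 and 0.07, and Ifng by -1.93 and 0.17. The change in CD3-rich cluster shares alone gives -1.90, -1.75 and -1.90 for these genes. For others of the 68, chosen after their values were seen, it gives less of the change observed in CD3-rich cells: -0.32 of -2.03 for Borcs7, 0.37 of 2.22 for Rgs1, -0.02 of 2.91 for Myo6 and 0.01 of -1.44 for Klrg1. For the B-like cluster 4 the effect differed for 6 of 6372 genes and for cluster 8 for 2 of 6632, each with 10 to 33 cells per library. The Alt Ext libraries were not tested against each other (1 female, 1 male), and apart from the sex-linked genes Alt Ext 1 showed the larger rises of Il4, Il13 and Il5 in CD3-rich cells and Alt Ext 2 the larger falls of Zeb2 and Cx3cr1.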

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

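Of the tests in this part, those of the male library and of chance repeats of a barcode, the bootstrap intervals of the make-up test and the comparison of cluster 7 with the CD3-rich cells were chosen only after the result was seen.

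The changes in the pooled CD3-rich cells could arise in part from the cluster make-up, since cluster 3 was larger and cluster 0 smaller in both Alt Ext libraries. With each cluster held at its PBS profile and only the shares of UMIs moved, the expected median log2 change was 56.9% of that observed for 171 genes that rose (47.9 to 67.9 over 1000 bootstrap draws) and 45.6% for the 104 that fell (33.6 to 60.7). For the genes that fell, 45.6% met the rule set beforehand against make-up alone, but the interval chosen afterwards reaches above 50%. For the genes that rose, make-up alone and changes within clusters cannot be told apart. Both intervals lie under the 75% set for make-up alone and both include the 50% below which it was to be excluded. A shift inside a cluster, as between the Foxp3 and Il4 groups of cluster 3, counts here as change within clusters. The test therefore covers only make-up by the main clusters. It left out 6 rises without a PBS count, and its genes were taken for their change in these same libraries. For type 2 genes the male library alone is argued against: between the female libraries, PBS 1 and Alt Ext 1, the fixed type 2 list had a median log2 difference of 2.48 (bootstrap 1.89 to 3.39), with 15 of 15 genes above 0. A difference between animals other than treatment stays open and untested, with 1 PBS library.

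Lower Cd74 in the NK-like cluster 7 of Alt Ext may come from droplets that also hold a T cell or another cell: without the cells that have a Cd3e, Cd3d or Cd3g UMI the log2 ratio moved from -2.46 (-3.24 to -1.75) to -0.18 (-1.47 to 1.19). Of the 73 Cd74 UMIs of PBS, 64 were in such cells and 61 in 1 cell, so the change rests mostly on that cell. For free RNA of B cells, 4 Cd79a and Ms4a1 UMIs (1.09 to 10.2) were seen where the ratio in B-like cells needs 11.8. This met the rule set beforehand against free RNA as the source of all 73 UMIs. The needed number counts the 61 UMIs of 1 cell, so the test cannot decide on free RNA for the other UMIs. No biological explanation was tested.

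Cell barcodes found in more than 1 library are likely not chance repeats: 16 library pairs shared a barcode against 1.17 by chance (up to 4 by the Poisson range). A candidate explanation is reads of a deep cell assigned to another library. At equal depth the deep partner lay at the median percentile of 99.7 among the cells of its library in likeness to the shallow copy, over the 6 of 12 pairs with a depth ratio of at least 10, and ranked first in 3 of these. A shallow PBS copy of an Alt Ext 1 cell held 2 of the 3 Il13 UMIs of PBS. The 6 pairs of like depth all lay in cluster 8 and ranked first in likeness in 6 of 6, and their source stays open.

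The effect of Alt Ext differed between cell sets in an edgeR test of the difference, for 6 genes between CD3-rich cells and the B-like cluster 4, 2 genes with cluster 8 and 68 genes with the NK-like cluster 7. As log2 differences, other set minus CD3-rich cells, cluster 4 gave Hist1h2ap -3.34, Ccl5 -2.23, Gzmb -3.87, AW112010 -2.11, Nkg7 -2.34 and Gzma -3.00. In that cluster Cd3e was found in 18 of 33 PBS cells, against 2 of 10 and 5 of 22 in Alt Ext, so RNA of T cells in these droplets may differ as well. Detection was not compared at equal depth, and these cells had medians of 5933, 3315.5 and 2534 UMIs. Cluster 8 gave Irf8 -4.79 and Ccl5 4.12. For Ccl5 this rests on Alt Ext 1 (156 CPM in PBS, 2032 in Alt Ext 1 and 165 in Alt Ext 2), and Cd3e was found in 3 of 10, 5 of 12 and 4 of 18 of these cells. Cluster 7 gave Gzma 2.17, Zeb2 2.41, Ifng 2.12, Borcs7 2.40 and S1pr5 2.16, and Ifi27l2a -2.75, Cd74 -3.13, Pop5 -1.58 and Lat -1.06. The fitted values of Klra8 (-6.25), Hid1 (4.93) and Areg (-5.03) are not folds to rely on: Klra8 had 0 CPM in PBS CD3-rich cells, against 6.75 and 12.5 in Alt Ext. In cluster 7 Hid1 had 2.47 CPM in PBS against 29.1 and 11.3, and Areg 12.4 against 0 and 2.27. The pooled CD3-rich cells carry their change in cluster make-up into each of these differences. Among data outside the comparisons, 19.6% of Alt Ext 1 barcodes had at least 10% mitochondrial UMIs, above the 6.40% of PBS 1.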

How the results depend on the processing

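Leaving out shared barcodes, cluster 3 or the CD3-positive cells of cluster 7, the bias-adjusted edgeR test and clusters made without the called genes are tests chosen only after the result was seen. No paired analysis was possible for Alt Ext against PBS because there is 1 PBS library, and without an Alt Ext library no call can be made, so folds alone are given. Of simulated genes changed by 1 on the log2 scale, cluster 3 recovered 6.59% and cluster 6 recovered 44.2%. Called named genes had 1445 values under other settings, of which 1098 kept direction and call, 345 kept direction only and 2 reversed. For named genes not called, 986 of 1023 values stayed so and 37 passed. Without 1 Alt Ext library, 191 of 224 values of called named genes moved by less than the spread, 29 moved by more and 4 reversed. List medians kept direction in 52 of 52 under library size scaling. Without 1 Alt Ext library, 70 of 104 list medians moved by less than the spread, 32 moved by more and 2 reversed. Leaving out mitochondrial and ribosomal genes changed no count of calls by more than 1.5 times (most in cluster 1, 3 against 2), and cluster 6 has no match at resolution 0.5. Apart from the tests of flagged results above, causes were not tested, also where a setting leaves out cells or genes. The fitted prior degrees of freedom moved along with several counts of calls. They went from 13.1 to 5.19 over all cells with scrublet calls removed (86 calls to 2). With at least 30 counts they went from infinite to 3.35 in cluster 3 (62 to 0) and to 8.36 in cluster 7 (19 to 1). In other settings the count moved while they stayed infinite, as in cluster 7 without CD3-positive cells (19 to 8).

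Called genes over all cells (86) were 140 with DESeq2 size factors, 47 with library size, 27 with DESeq2, 281 with no filter, 179 with the stricter cell filter, 2 with scrublet calls removed, 201 with equal cell numbers, 44 without shared barcodes, 48 with the bias-adjusted test and 176 without cluster 3. In CD3-rich cells (281) they were 34 with DESeq2 and 153 without cluster 3. Cluster 1 (2) gave 0 with DESeq2, 4 with no filter, 1 with at least 30 counts, 0 at resolution 2, 1 with equal cell numbers and 5 with the bias-adjusted test. Cluster 2 (7) gave 0 with DESeq2, 4 with the stricter cell filter, 12 at resolution 0.5, 0 at resolution 2 and 14 with the bias-adjusted test. Cluster 3 (62) gave 0 with DESeq2, 27 with no filter, 0 with at least 30 counts, 4 at resolution 0.5 and 39 with equal cell numbers. Cluster 6 (14) gave 0 with DESeq2, 5 with the stricter cell filter and 0 at resolution 2. Cluster 7 (19) gave 0 with DESeq2, 1 with at least 30 counts, 11 with equal cell numbers and 8 without CD3-positive cells. Lists called in every cell set came to 0 with an estimated correlation and 0 by fry. With 1 residual degree of freedom, the estimated correlation cannot decide on a list.

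Reversed were Klra8 in CD3-rich cells at resolution 2 (-0.54) and Cd74 in cluster 7 with scrublet calls removed (0.23). Without 1 Alt Ext library, values in cluster 6 ran from -2.31 to 3.54 for Cd74, -4.31 to 4.73 for H2-Aa, -1.32 to 4.39 for H2-Ab1, 0 to 8.27 for H2-Eb1 and -1.82 to 4.56 for the MHC class II median. The interferon median in cluster 1 ran from -0.59 to 0.019.

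By markers per cell, a cluster stands for the cells that score highest on a marker list set beside it. The list is that of CD8 T cells for cluster 0 and of classical monocytes or interstitial macrophages for cluster 8. These can be other cells than the cluster. Share differences (Alt Ext mean minus PBS, percentage points) were, for cluster 0 (-16.7), -10.7 by markers per cell. Cluster 3 (16.2) held 32 of 570 cells of PBS 1, 60 of 353 of Alt Ext 1 and 62 of 513 of Alt Ext 2 by markers. Cluster 2 (-2.46) gave 0.826 without the called genes, 0.605 at resolution 0.5 and -1.19 at resolution 2. Cluster 5 (0.311) gave 0.637 with the stricter filter, 0.317 without shared barcodes, 0.394 without the called genes, 0.213 and 0.505 at resolutions 0.5 and 2, 1.48 by markers and 0.384 with scrublet calls removed. Cluster 6 (3.14) gave 0.965 without the called genes, 0.551 at resolution 2, and held 4.04%, 6.80% and 3.90% by markers. Cluster 8 (1.70) gave 1.52 with the stricter filter, 1.56 without shared barcodes, 1.88 at resolution 2, -0.990 by markers and 1.79 with scrublet calls removed. Cluster 9 (3.17) gave 3.39 with the stricter filter, 2.96 without the called genes, 2.82 at resolution 2 and 2.83 by markers. Ifng-positive cells (-11.2) gave -5.30 at 2 UMIs and -3.74 thinned, and Foxp3-positive cells (5.79) 3.54 and 3.74.

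Type 2 against type 17 cells (31 calls) gave 16 with no replicate block, 173 with fine clusters picked by Il13 or a type 17 marker and 3 to 48 without 1 library. CD3-rich cells against cluster 7 (1049) gave 692 to 1230 without 1 library, and cluster 3 against cluster 1 (1047) 1592 with library size and 611 to 1073 without 1 library. Metabolic lists called were 3 by clusters for the first pair (0), 0 with an estimated correlation and up to 2 without 1 library for the second (1), and 0 with an estimated correlation for the last (2). The difference test with cluster 8 (2) gave 6 with library size.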

Other observations

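Apart from the camera tests between fine clusters at Leiden resolution 2, the values in this part were not tested. In the ILC2-like cluster 5 (16, 11 and 16 cells of PBS 1, Alt Ext 1 and Alt Ext 2; median 2279, 3540 and 4729 UMIs), Il13 had 0, 4 and 99 UMIs, or 0, 0.779 and 14.4 per 10000 UMIs, and 92 of the 99 came from 1 cell. The CD3-rich cells had 3, 147 and 51 Il13 UMIs.

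Glycolysis transcripts made up 32.4, 48.5 and 43.9 per 10000 UMIs in the CD3-rich cells and one-carbon transcripts 2.46, 3.84 and 4.48. Most other metabolic lists were higher there too: the TCA cycle gave 13.5, 16.6 and 16.7, nuclear oxidative phosphorylation 147, 183 and 169, glutaminolysis 4.99, 6.11 and 6.25, fatty acid oxidation 6.02, 8.07 and 8.74, and fatty acid and sterol synthesis 2.34, 3.71 and 3.07. Mitochondrially encoded oxidative phosphorylation gave 266, 266 and 307. By cluster, glycolysis transcripts made up 59.4, 68.6 and 61.7 per 10000 UMIs in the proliferating cluster 9, 49.1, 57.7 and 58.2 in cluster 3, 32.6, 28.2 and 32.6 in the NK-like cluster 7 and 22.9, 23.2 and 23.8 in cluster 1. One-carbon transcripts made up 9.18, 8.29 and 10.9 in cluster 9 against 1.72, 1.70 and 1.80 in cluster 1. Nuclear oxidative phosphorylation gave 198, 225 and 226 in cluster 9 and 119, 127 and 122 in cluster 1.

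At Leiden resolution 2, the clusters that overlap cluster 3 most were a group led by Foxp3, Ctla4 and Ikzf2 (93 cells; Il4 in 3.23% of cells) and a group led by Il4, Lgals7, Igfbp7 and Epas1 (73 cells; 3, 47 and 23 cells; Foxp3 in 4.11%, Gata3 in 89.0% and Il4 in 53.4% of cells) and a group of 80 cells. The Il4 group against the fine cluster of Cd163l1 and Blk cells (46 cells), within the Alt Ext libraries only, passed for glycolysis (median 0.62, camera adjusted p = 0.0016), nuclear oxidative phosphorylation (0.28, adjusted p = 0.00553) and mitochondrially encoded oxidative phosphorylation (-0.45, adjusted p = 0.0016), each with adjusted p = 0.515 under an estimated correlation.

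Cd3e was found in 18 of 33, 2 of 10 and 5 of 22 B-like cells. B-like PBS cells with it had a median of 6587 UMIs, against 3305 without. Barcodes left out for mitochondrial UMIs had medians of 741, 897 and 827 UMIs, and 11, 16 and 8 of them held Cd3e.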
